A study of Mus musculus with 2 samples.

How the data were processed

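The deposited matrices of 2 mouse lung libraries, Cherry_positive and Cherry_negative, hold counts of UMIs per gene and barcode, per the labels, for 27998 gene IDs. The submitters' processing notes name Cell Ranger 2.1.1 with mm10, Seurat 4.0.2 and R 4.0.3, and parameters beyond these are not given in the sources used here. The labels name Chromium 3' libraries, a HiSeq4000 and a target of 50000 reads per cell. The comparison, the class markers, the 27 gene lists and the first alternatives were written down before the data were examined.

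Counts were read with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Cells with under 500 genes or over 10% mitochondrial UMIs were left out, 56 in the Cherry_positive and 50 in the Cherry_negative library. Scrublet as in scanpy 1.11.5, with an expected rate of 2%, called 4 (0.226%) and 7 (0.249%) doublets, which were removed, and so few calls leave open that doublets remained. The 1766 and 2804 kept cells were clustered together on 2000 variable genes, 30 principal components and 15 neighbours with leidenalg 0.10.2 at resolution 1 and seed 0, without batch correction, which gave 25 clusters. Figures were drawn with matplotlib 3.10.9.

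Clusters were named with 31 marker classes. A marker counted as detected in a cluster at 10% of cells and 10% of its highest level over clusters, at least 3 detected markers were needed, and the 10 leading genes, ranked by fold with 10 CPM added among genes of at least 50 CPM, could not hold more markers of another lineage than of its own. This naming rule replaced an earlier one after the clusters had been seen, and it left clusters 10 and 24 unnamed. Of the genes sought, the markers Gucy1a1, Trbc2, Ighm and Igkc and the list member Gbp6 could not be used, and 121 symbols were shared by several IDs. The marker Ccl21a, such a shared symbol, was used in naming clusters. Gene positions came from GENCODE M21.

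Classes with at least 50 cells in each library were compared, namely alveolar fibroblasts, adventitial fibroblasts, myofibroblasts, pericytes, general capillary and Car4 capillary cells. UMIs were summed over the cells of a class and divided by all UMIs of the class. Sums carry exact 95% Poisson intervals, ratios the interval of the matching binomial share, and shares of cells exact binomial intervals. For 0 cells the limit of 3 counts of the total was also given. Genes with 0 UMIs on 1 side were set against a floor of 3 counts. With 1 library per group, no p-value was computed.

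Genes were named by rule. Genes with at least 30 UMIs over both libraries and 20 CPM in either were ranked by the bound of the ratio interval nearest 1, and 12 each way were named in alveolar fibroblasts and general capillary cells, the classes with most cells of their lineage, and 5 each way in the others. Mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes, and genes 10 times higher in another lineage of the library with the higher level, were left out. Members of the gene lists could be named in any compared class.

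A list was measured over members with at least 10 UMIs and needed 3 of them. Its value was the median log2 ratio with 0.5 added to each count, with an interval from 1000 Poisson redraws and a percentile among 10000 random lists matched in 20 expression bins. Lists were interferon gamma response, type I interferon response, MHC class I, MHC class II, inflammatory cytokines and acute phase, TGF-beta targets and extracellular matrix, neutrophil granule, Notch pathway, Wnt pathway, YAP and TAZ targets, p53 targets, G1/S, G2/M, lung progenitor, injury transitional epithelium, activated or angiogenic endothelium, alveolar niche growth factors, glycolysis and hypoxia, oxidative phosphorylation nuclear, mitochondrial transcripts, unfolded protein response, oxidative stress response, dissociation stress, surfactant and AT2 lipid, AT1 genes, club cell secretory, and haemoglobin. Cycling cells were those with at least 2 G2/M UMIs after thinning to 2000 UMIs, and shallower cells were left out.

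The method was tested on simulated data with 200 changed genes per class. Class sums were drawn by Poisson sampling, the model that the intervals assume, without spread between cells or between libraries. The rates below therefore check the computation and do not measure the error on these data. In alveolar fibroblasts, with 9586 genes, it found 83% of 2-fold and 93% of 4-fold changes, 3.80% of unchanged genes had an interval off 1, and 96.2% of intervals held the true ratio. In general capillary cells, with 7357 genes, these were 64%, 81%, 3.94% and 96.0%. A list with a true log2 ratio of 1 came out at 0.96 and 1.03, and of 200 unchanged lists 3% and 4% lay outside the central 95% of random lists. In Car4 capillary cells 7.5% did.

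Alternatives were no cell filter, doublets kept, resolution 0.5 and 2, at least 1000 genes with at most 5% mitochondrial UMIs, separate clustering of the libraries, 5% of free RNA subtracted, list members with at least 50 UMIs or 1 UMI, lists without members 10 times higher in another lineage, a trimmed-mean factor, median of ratios scaling, equal weight of cells, and cells thinned to 2000 UMIs. For cycling cells they were no thinning, thinning to 1000 UMIs and at least 3 G2/M UMIs. Single clusters, the data without cluster 10, and genes without their top cell were added after the data had been seen. Free MHC class II RNA of AT2 cells was likewise worked out later, as their MHC class II level times the median level of Sftpa1, Sftpb, Sftpc and Sftpd in a class relative to AT2 cells.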

Results

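Single-cell RNA sequencing was done on CD45-negative cells, that is cells without the surface protein carried by leukocytes, from dissociated mouse lungs taken 7 days after labelling 4T1 cells were injected into a vein. 4T1 is a mouse mammary carcinoma line that colonises the lung. Labelling 4T1 cells are known as a version that releases a cell-penetrating mCherry protein which neighbouring cells take up. The labels give 2 groups of cells sorted by flow cytometry, Cherry_positive and Cherry_negative, with 1 library each. They do not say whether these mice had been irradiated. The Cherry_positive library held 1826 barcodes with 10094853 UMIs in all and a median of 4324 per barcode. The Cherry_negative library held 2861 barcodes with 11632459 UMIs and a median of 2971. Filtering left 1766 and 2804 cells. With 1 library per group there were no replicates and no test was made, so each difference compares these 2 libraries. Each interval is a 95% interval for counting error only. Levels are in CPM, the usual scaling of the UMIs of a gene to the total of its class. Gene positions are those of GRCm38 (mm10). The comparisons ask which lung cells carried the Cherry label, and which transcripts differed in level between Cherry-positive and Cherry-negative cells of the same class.

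Fibroblasts and other mesenchymal cells made up 74.0% (71.9 to 76.0) of the Cherry_positive library against 27.4% (25.7 to 29.04) of the Cherry_negative library. Endothelial cells were less frequent with the label, with 14.0% (12.4 to 15.7) against 51.5% (49.7 to 53.4). Epithelial cells were less frequent too, with 2.27% (1.62 to 3.07) against 18.7% (17.3 to 20.2). Cells like alveolar fibroblasts, which line the alveolar wall and express Tcf21 and Npnt, were 49.2% (46.8 to 51.5) of Cherry-positive and 16.0% (14.7 to 17.5) of Cherry-negative cells, a ratio of 3.06. Myofibroblast-like cells were at 11.4% against 4.71%. Adventitial fibroblast-like cells, which surround vessels and airways, were at 7.19% against 4.07% and pericyte-like cells, which wrap capillaries, at 3.57% against 1.78%. Cells like type 2 alveolar epithelial (AT2) cells, which make surfactant, were 1.25% (0.782 to 1.88) against 15.9% (14.6 to 17.3), that is 22 against 447 cells.

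Among endothelial cells, the general capillary-like class was 6.06% (4.99 to 7.27) of the Cherry_positive and 27.7% (26.0 to 29.4) of the Cherry_negative library. The Car4 capillary-like class, the thin cells of the gas exchange surface, was 4.42% (3.51 to 5.48) against 10.6% (9.51 to 11.8). Arterial cells (1.76% against 9.95%) and venous cells (0.453% against 3.10%) were also scarcer with the label. In contrast, lymphatic cells were more frequent, at 1.30% (0.827 to 1.95) against 0.178% (0.0579 to 0.416). The remaining classes were AT1 cells at 0.283% against 2.03%, club cells at 0.736% against 0.749% and smooth muscle cells at 0.340% against 0.713%. Outside these lineages there were mesothelial cells at 0.623% against 0.428%, macrophages or monocytes at 0.906% against 0.392% and other immune cells at 0.849% against 0.642%. A further mesenchymal cluster matched no single class and held 42 Cherry-positive cells and 1 Cherry-negative cell. Clusters 10 and 24 stayed unnamed. The first had 128 cells (7.25%, 6.08 to 8.56) against 10 cells (0.357%, 0.171 to 0.655) and the second 2 against 16 cells. The mCherry gate separates the groups and the CD45 depletion took out most leukocytes before sequencing, so these are shares of sorted cells, not of the lung.

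**Figure D1:**
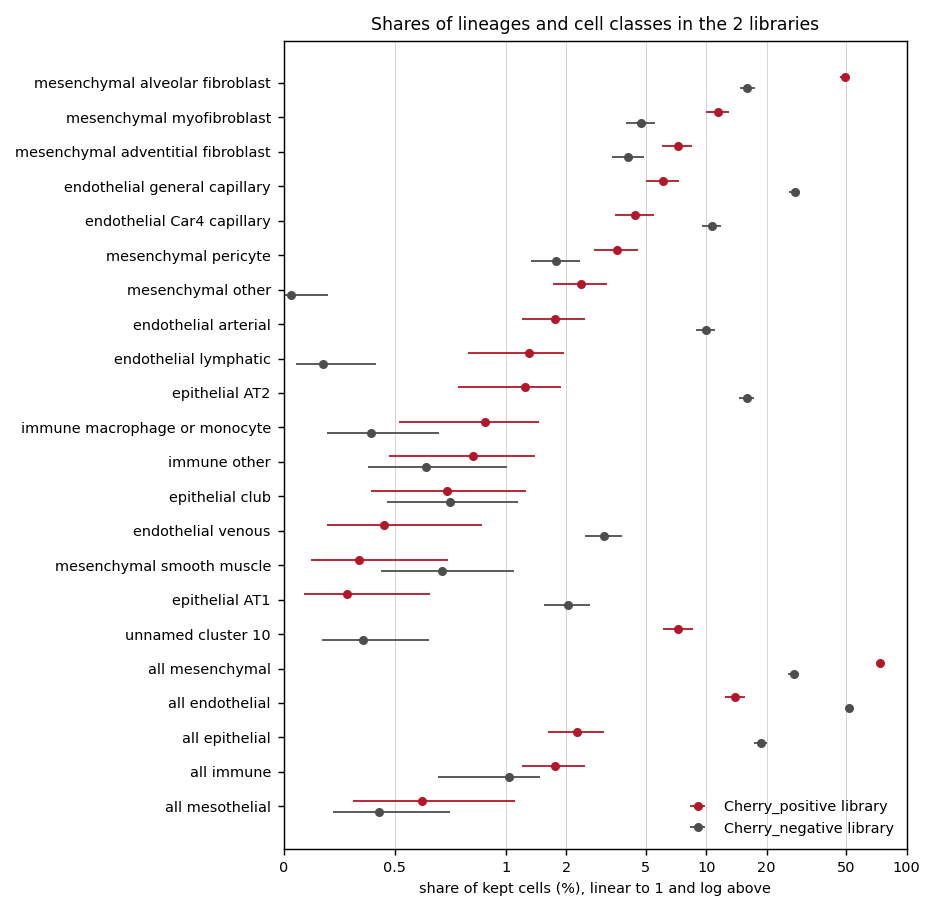
Share of kept cells (%, horizontal axis, linear to 1 and logarithmic above) in each class and lineage, with points for the Cherry_positive (red) and Cherry_negative (grey) libraries and bars for exact 95% binomial intervals. Mesenchymal cells lie at 74.0% against 27.4% and endothelial cells at 14.0% against 51.5%.

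Alveolar fibroblasts of the Cherry_positive library held far more RNA of chemokines and of genes induced by interferon gamma. Cxcl10 (chromosome 5, 92346638 to 92348889) stood at 3694 CPM (3638 to 3750) against 129 (111 to 148), a ratio of 28.7 (24.9 to 33.2). Its neighbour Cxcl9 (chromosome 5, 92321347 to 92328079) stood at 702 CPM (678 to 727) against 8.55 (4.55 to 14.6), a ratio of 82.2 (48.0 to 154), although all 13 Cherry-negative UMIs of Cxcl9 came from 1 cell. Both encode chemokines that attract lymphocytes through Cxcr3. Ccl7, which attracts monocytes, was at 973 against 22.4 CPM. The T cell attractant Ccl5 was at 205 against 1.97 with a ratio of 104 (35.4 to 504) over 3 Cherry-negative UMIs, and the B cell attractant Cxcl13 at 173 against 3.29. Fst (chromosome 13, 114452290 to 114458951), which encodes the activin antagonist follistatin, had 845 UMIs against 0, so it was at least 93.5-fold higher against a floor of 3 counts. Of 868 Cherry-positive cells 78 held Fst UMIs and 59 held Cxcl13 UMIs, with 26.5% of the latter in 1 cell.

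The other genes named on the higher side were the antiviral gene Rsad2 with a ratio of 103 (18.4 to 4089), Ubd, a ubiquitin-like gene induced by interferon gamma, with 96.2 (17.1 to 3814). The interferon-inducible Fam26f had a ratio of 29.8 (17.4 to 56.2), Gm15056 of 29.8 (10.1 to 145), the acute phase gene Saa1 of 29.2 (9.88 to 143) and the guanylate-binding protein gene Gbp4 of 25.5 (16.8 to 40.7). Rsad2, Ubd and Saa1 were seen in 48, 59 and 36 of 868 Cherry-positive cells. On the lower side, Igfbp3 (chromosome 11, 7206086 to 7213923), which encodes a carrier of insulin-like growth factors, was at 53.2 CPM (46.8 to 60.3) against 407 (376 to 440), 7.65-fold lower. Slc7a10, an amino acid transporter gene and a marker of this class, was at 99.7 against 503 CPM, Mettl7a1 at 258 against 1097, and Pcolce2, which encodes an enhancer of procollagen processing, at 519.9 against 1946. The remaining lower genes, each 4.89-fold to 8.54-fold lower, were Fam222a, Syt17, Gm14964, Fam189a2, Ptprb, Shisa2, Cox8b and Ccdc42. Ptprb, whose product is an endothelial phosphatase, was also among the lower genes of adventitial fibroblasts and Car4 capillary cells.

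**Figure D2:**
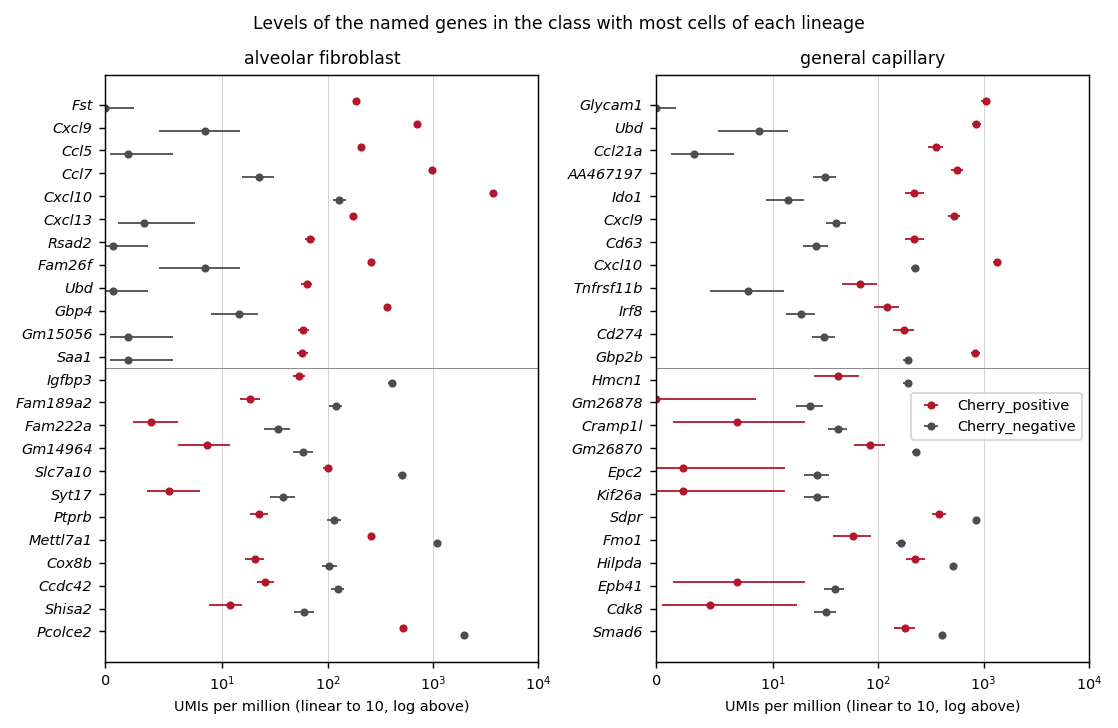
CPM (horizontal axis, linear to 10 and logarithmic above) of the genes named by rule in alveolar fibroblasts (left) and general capillary cells (right), with points for the 2 libraries and bars for exact 95% Poisson intervals. Genes above the line were higher in the Cherry_positive library, such as Cxcl10 at 3694 against 129 in alveolar fibroblasts, and genes below it were lower, such as Igfbp3 at 53.2 against 407.

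Whole gene groups moved with these genes in alveolar fibroblasts. All 14 measured members of the interferon gamma list were higher, with a median log2 ratio of 2.31 (2.06 to 2.49), at percentile 100 of 10000 random lists matched on size and expression, which describes these libraries only. The type I interferon list had a median of 1.52 (1.24 to 1.67) with 18 of 18 members higher. Among them were the ubiquitin-like Isg15 at 541 against 92.0 CPM and Irf7, a regulator of interferon genes, at 139 against 32.9. The MHC class I list, the genes that load and present peptides to cytotoxic T cells, had a median of 1.35 (1.23 to 1.50) with 14 of 14 higher. B2m was at 5886 against 2874 CPM and the peptide transporter Tap1 at 193 against 41.4. The MHC class II list had 0.87 (0.52 to 1.27) with 6 of 6 higher at low levels, for example H2-Ab1 at 45.6 against 17.1 CPM. The list of inflammatory cytokines and acute phase genes had 2.02 (1.85 to 2.33), or 1.88 with the member at 0 placed at its bound, and 16 of 16 were higher. It was 3.37 with the libraries clustered separately and 1.59 without members 10 times higher in another lineage. Its members included the acute phase gene Saa3 at 7774 against 1018 CPM, the monocyte attractant Ccl2 at 2172 against 408, the neutrophil attractant Cxcl1 at 1038 against 344 and Il6 at 548 against 195. Lcn2, which encodes an iron-sequestering protein of neutrophil granules and inflamed tissue, was at 864 against 189 CPM. It set the median of the neutrophil granule list, 2.19 (1.54 to 2.52) with 5 of 5 higher. The other 4 of those, S100a8, S100a9, Prtn3 and Mmp8, lay between 10.3 and 14.8 CPM in the Cherry_positive library.

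Matrix genes were higher too, with a median of 0.94 (0.71 to 1.06) over the list of TGF-beta targets and extracellular matrix and 20 of 23 members higher. The protease inhibitor Timp1 was at 2190 against 247 CPM, and the matricellular gene Tnc at 236 against 38.8. Thbs1 was at 1231 against 353 and the collagen gene Col3a1 at 2117 against 1172, but the elastin gene Eln was at 1015 against 1079. Of the lung progenitor list 8 of 10 members were higher, with a median of 0.91 (0.55 to 1.65), or 0.84 with the member at 0 placed at its bound. Its stem cell antigen gene Ly6a was at 628 against 141 CPM and the hyaluronan receptor gene Cd44 at 180.2 against 47.3, but Aldh1a1, a retinal dehydrogenase gene, at 314 against 800.1. The injury transitional list had 0.66 (0.51 to 1.16), the unfolded protein response list 0.49 (0.38 to 0.60), the glycolysis and hypoxia list 0.36 (0.20 to 0.48) and the oxidative stress list 0.33 (0.25 to 0.83). The immediate early genes of the dissociation stress list were lower, at -0.48 (-0.54 to -0.45), such as Fos at 3533 against 6146 CPM and Jund at 1114 against 2783.

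Different clusters held most of this class in each library. Of 868 Cherry-positive alveolar fibroblasts, 269 were in cluster 7, 266 in cluster 8, 209 in cluster 6 and 124 in cluster 2. Of 450 Cherry-negative ones, 325 were in cluster 2, 91 in cluster 6, 28 in cluster 7 and 6 in cluster 8. Chemokine and interferon genes, among them Cxcl9, Cxcl10, Ccl7 and Rsad2, were among the genes that define cluster 8, and Fst and Tnc among those of cluster 7. Clusters 7 and 8 had 0 mesenchymal markers among their 10 leading genes. They were placed in this class by 7 and 5 detected class markers, so their place in it is less secure. Within cluster 2 by itself the interferon gamma list had a median of 0.25, the MHC class I list 0.20 and the inflammatory list 0.86. Within cluster 6 these were 1.13, 0.18 and 1.001. Other lists turned sign there, MHC class II to -1.95 in cluster 2 and -0.55 in cluster 6, the lung progenitor and glycolysis lists to -0.0307 and -0.0757 in cluster 2, and the injury and dissociation stress lists to -0.15 and 0.0914 in cluster 6. These clusters were taken by themselves after the data had been seen. Taking them alone leaves out cluster 8, which tends to lower the interferon and MHC medians by construction. The injury median was also -0.0904 without members 10 times higher in another lineage. A trimmed-mean scaling factor would raise all log2 ratios by 0.12 in alveolar fibroblasts, 0.16 in myofibroblasts and 0.27 in pericytes.

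Chemokine genes were also among the higher genes of the other compared mesenchymal classes, with Cxcl9 in each of them and the rest differing by class. Free RNA of alveolar fibroblasts, 49.2% of the Cherry_positive library, was not screened here, because genes were set against other lineages only. It remains open for genes at lower levels in these classes than in alveolar fibroblasts. Cxcl10 and Cxcl9 of pericytes stood above the 3694 and 702 CPM of alveolar fibroblasts. In pericytes Cxcl10 was at 5878 CPM (5570 to 6198) against 377 (278 to 500) and Cxcl9 at 2963 (2745 to 3193) against 70.7 (32.3 to 134), of whose Cherry-negative UMIs 1 cell held 68.8% and 88.9%, with Ccl5 at 379 against 7.85. Saa3 and Ubd were seen with 189 and 50 UMIs against 0, at least 34.6-fold and 9.15-fold higher. A single cell held 84.1% of those Saa3 UMIs, and a single cell held 60.2% of the Ccl5 UMIs. In adventitial fibroblasts Ccl2 was at 1148 CPM (1078 to 1223) against 63.0 (43.9 to 87.7), Cxcl10 at 522 against 23.4, and the metal-binding Mt2 at 4367 against 611. Cxcl9 and the neutrophil attractant Cxcl5 had 63 and 37 UMIs against 0, at least 13.6-fold and 8.01-fold higher, with 66.7% of the Cxcl9 UMIs in 1 cell. In myofibroblasts Ccl2 was at 1260.1 CPM (1189 to 1334) against 187 (144 to 237) and Saa3 at 621 against 2.83. Of the Ccl2 UMIs 1 cell held 39.0% in the Cherry_positive and 1 cell 66.7% in the Cherry_negative library, and of the Cherry-positive Saa3 UMIs 1 cell held 41.4%. The matrix gene Postn was at 119.5 against 2.83 and Fst at 124 against 5.65, and Cxcl9 had 59 UMIs against 0, at least 7.49-fold higher with 74.6% of them in 1 cell. Over few Cherry-negative UMIs the ratios were 220 (39.3 to 8697) for Saa3, 42.3 (7.43 to 1685) for Postn and 21.9 (5.93 to 183) for Fst in myofibroblasts, and 48.3 (8.45 to 1930) for Ccl5 in pericytes.

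On the lower side, myofibroblasts had less Angpt2, an antagonist of the endothelial receptor Tie2, at 18.3 against 102 CPM, with Adam33, Gstk1, Scn7a and Efnb2 between 5.53-fold and 7.87-fold lower. Adventitial fibroblasts had less Inmt, a methyltransferase gene that marks alveolar fibroblasts, at 856 against 2541 CPM. They also had less Pdgfa, a growth factor gene for fibroblasts, at 12.9 against 61.2, less Omd, a small proteoglycan gene, at 12.9 against 64.8 and less Ptprb at 30.4 against 148. A single Cherry-negative cell held 63.9% of the Omd UMIs. Cytl1 had 0 against 165 UMIs, at least 84.7-fold lower, from 2 cells. In pericytes the 5 lowest genes were endothelial ones, among them Icam2 with 1 against 37 UMIs (ratio 0.0148, 0.000366 to 0.0880) and Car4 with 1 against 36 (0.0153, 0.000376 to 0.0906). A single Cherry-negative cell held 62.2% of those Icam2 UMIs, and 1 cell held 58.3% of those of Car4. The others were Egfl7 at 17.2 against 432 CPM, the tight junction gene Cldn5 at 51.7 against 848 and Tmem100 at 34.5 against 495. In the Cherry_negative library 51.5% of all cells were endothelial.

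The interferon gamma list had medians of 1.98 (1.67 to 2.45) in pericytes with 14 of 14 members higher. It had 1.58 (1.30 to 2.04) in adventitial fibroblasts with 13 of 14, or 1.42 with zero members at their bound, and 1.38 (0.72 to 1.53) in myofibroblasts with 12 of 13. The type I interferon list followed with 1.30 (1.14 to 1.94), 1.22 (0.96 to 1.56) and 0.57 (0.37 to 0.81). The MHC class I list had 1.29 (1.14 to 1.44), 0.49 (0.30 to 0.66) and 0.54 (0.30 to 0.73). MHC class II was lower in myofibroblasts, at -0.91 (-1.49 to -0.17) with 4 of 4 measured members lower and Cd74 at 22.6 against 39.6 CPM. These 4 members summed to 62.5 against 113 CPM in myofibroblasts. Surfactant genes of AT2 cells, which also express MHC class II, were lower in the same cells, and free RNA of AT2 cells at the level of the surfactant proteins would bring 7.08 against 60.9 CPM of these members. The MHC class II median was -1.07 (-1.85 to 0.22) in adventitial fibroblasts, with 43.3 against 79.3 CPM and 6.97 against 58.6 CPM from such free RNA. Inflammatory genes had 1.28 (0.88 to 2.24) in myofibroblasts, 0.61 (0.43 to 1.11) in adventitial fibroblasts and 0.31 (0.16 to 1.82) in pericytes. In the same order, matrix genes had 0.87 (0.70 to 1.06), -0.07 (-0.16 to 0.18) and 0.15 (-0.04 to 0.41). Growth factors of the alveolar niche were lower in myofibroblasts, at -0.80 (-0.99 to -0.28) with 7 of 10 members lower. Fgf7, a growth factor for epithelium, was at 99.1 against 218 CPM and Bmp4, which encodes a bone morphogenetic protein, at 49.5 against 113. The list was also lower in adventitial fibroblasts, at -0.46 (-0.83 to -0.10). With each library clustered by itself the interferon gamma median of myofibroblasts was 0.25 and that of MHC class I -0.0375, and at resolution 0.5 that of MHC class II was 0.57. Without members 10 times higher in another lineage the interferon gamma median of adventitial fibroblasts was 0.93.

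**Figure D3:**
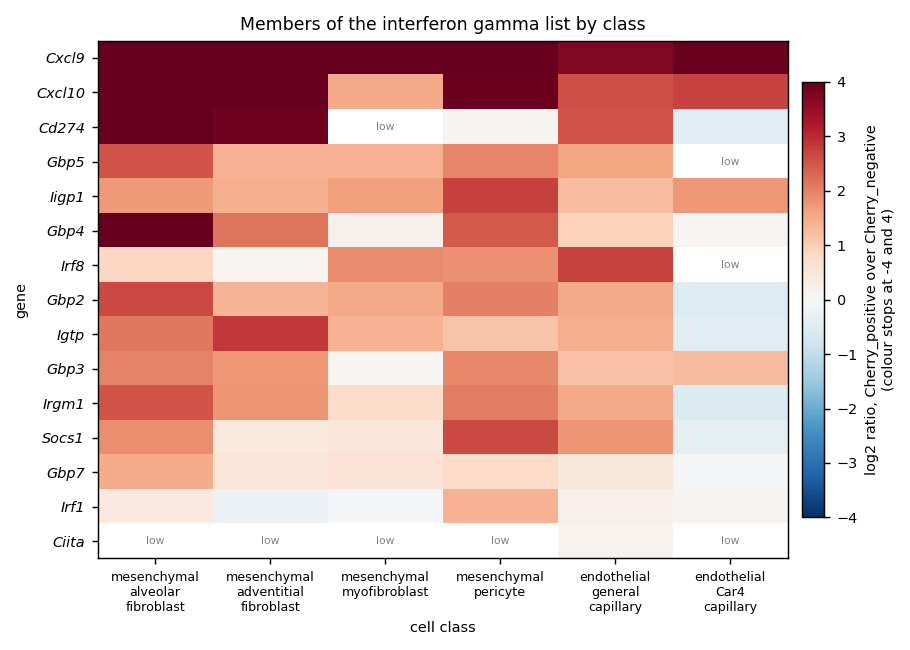
Log2 ratio of CPM, Cherry_positive over Cherry_negative, for each member of the interferon gamma list (vertical axis) in each compared class (horizontal axis), with red for higher and blue for lower, colours stopping at -4 and 4, and "low" for members under 10 UMIs. All 14 measured members were higher in alveolar fibroblasts and pericytes, and 6 of 12 were in Car4 capillary cells.

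General capillary cells of the Cherry_positive library also held more RNA of genes induced by interferon gamma. Ubd (chromosome 17, 37193892 to 37196095) was at 855 CPM (769 to 947) against 8.86 (5.33 to 13.8), a ratio of 96.5 (60.9 to 162). It was seen in 20 of 107 Cherry-positive cells, and 1 cell held 29.4% of those UMIs. Cxcl10 was at 1344 (1236 to 1458) against 224 (205 to 245) and Cxcl9 at 522 (456 to 595) against 40.1 (32.1 to 49.5). Ido1, which encodes an enzyme that breaks down tryptophan, was at 221 against 14.0 CPM, with 29.5% of its Cherry-positive UMIs in 1 cell. Cd274, the gene of the checkpoint ligand PD-L1, was at 175 against 30.8, the transcription factor gene Irf8 at 121 against 18.6, and Gbp2b at 838 against 191. The further higher genes were AA467197 with a ratio of 18.0 (13.7 to 23.9), the tetraspanin gene Cd63 with 8.63 (6.13 to 12.3) and Tnfrsf11b, the gene of osteoprotegerin, with 8.52 (4.53 to 16.5). Of the Cherry-positive Cd63 UMIs 1 cell held 31.6%. Glycam1, a ligand of L-selectin, had 451 UMIs against 0, all of them in 1 cell, and 93.4% of the 151 UMIs of 1 of the IDs of the lymphatic chemokine gene Ccl21a came from 1 cell as well.

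Lower in Cherry-positive general capillary cells were Hmcn1, which encodes a matrix protein, at 41.9 CPM (24.8 to 66.2) against 192 (174 to 211), and Smad6, an inhibitor of BMP signalling, at 179 (141 to 224) against 406 (379 to 433). The caveolar gene Sdpr was at 382 against 858, the lipid droplet gene Hilpda at 226 against 518, the monooxygenase gene Fmo1 at 58.2 against 165 and Gm26870 at 83.8 against 227. The membrane skeleton gene Epb41, Cramp1l, the kinase gene Cdk8, Epc2 and Kif26a were seen with 1 to 3 UMIs. Their ratios were 0.181 (0.0365 to 0.546), 0.168 (0.0341 to 0.508), 0.147 (0.0174 to 0.551) and, for each of the last 2, 0.0892 (0.00222 to 0.518). Gm26878 had 0 against 48 UMIs, at least 3.20-fold lower.

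The interferon gamma list had a median of 1.52 (1.29 to 1.63) in general capillary cells at percentile 100 of random lists, or 0.98 with the libraries clustered separately. By the sign used for lists 15 of 15 members were higher, although Ciita, the regulator of MHC class II, was at 9.31 against 9.32 CPM. MHC class II was higher with 0.76 (0.60 to 1.22), the invariant chain gene Cd74 being at 2422 against 828 CPM and H2-Eb1 at 317 against 131. So were type I interferon genes with 0.51 (0.38 to 0.60) and MHC class I with 0.45 (0.35 to 0.53). The Notch pathway list was lower at -0.45 (-0.79 to -0.20), percentile 0.660, with 10 of 12 members lower. The target gene Hey1 was at 109 against 260 CPM and the ligand gene Dll4 at 97.8 against 182. Both, like Smad6, were among the 10 leading genes of the arterial cluster 5. Arterial cells were 1.76% of the Cherry_positive and 9.95% of the Cherry_negative library, and the source of the Notch difference was not tested. The injury transitional list had 0.82 (0.45 to 1.30), with the calcium-binding S100a6 at 298 against 49.4 CPM and Clu, an extracellular chaperone gene, at 126 against 50.4. The G1/S list had 0.48 (0.15 to 0.79), the inflammatory list 0.37 (0.02 to 0.92), or -0.0467 with 5% of free RNA subtracted, and the matrix list 0.80 (-0.07 to 1.10). Cluster 0 held most of the class in both libraries, 66 of 107 Cherry-positive and 674 of 776 Cherry-negative cells. Cluster 12, which AA467197, Ido1, Ubd and Cd274 help to define, held 36 against 70. Within cluster 0 by itself the interferon gamma median was 0.13 and those of type I interferon, MHC class I and MHC class II were -0.43, -0.14 and -0.0710, values also computed after the data had been seen. Taking cluster 0 alone leaves out cluster 12, which tends to lower these medians by construction.

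In Car4 capillary cells the interferon gamma list had a median of -0.01 (-0.22 to 0.36), percentile 39.1, with 6 of 12 members higher. It was 0.39 with the libraries clustered separately and -0.59 with 5% of free RNA subtracted, although Cxcl10 was at 84.8 against 12.7 CPM. The lists of type I interferon and MHC class I genes had 0.05 (-0.14 to 0.36) and -0.13 (-0.19 to 0.01). MHC class II was lower, at -0.96 (-1.98 to -0.37) or -0.74 with the member at 0 placed at its bound, over 4 members, with Cd74 at 31.8 against 67.6 CPM. These summed to 70.6 against 141 CPM, and free RNA of AT2 cells at the level of the surfactant proteins would bring 5.82 against 69.3 CPM of them. The named higher genes were the hydrolase gene Abhd2 at 378 CPM (310 to 457) against 115 (94.5 to 139), the transcription factor gene Sox18 at 434 (361 to 518) against 207 (179 to 238). So were the netrin gene Ntn4 at 84.8 against 27.5, the calcineurin regulator Rcan1 at 67.1 against 20.1 and Frmd4b at 60.03 against 17.9. Lower were Ptprb at 60.03 CPM (35.0 to 96.1) against 206 (178 to 237) and Grtp1 and Msl3 with 1 UMI each against 46 and 45, ratios of 0.0727 (0.00180 to 0.426) and 0.0743 (0.00184 to 0.436). The muscle genes Acta2 and Tpm2 were lower too, but 1 Cherry-negative cell held 95.6% and 90.4% of the UMIs, and the log2 ratios without that cell were 1.74 and 0.60. The matrix list had 1.09 (0.35 to 1.63) with 11 of 12 members higher, mostly at low levels, such as Thbs1 at 38.8 against 5.28 CPM. The median became -0.13 when 5% of free RNA was subtracted. The inflammatory list had 0.38 (-0.10 to 0.76).

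**Figure D4:**
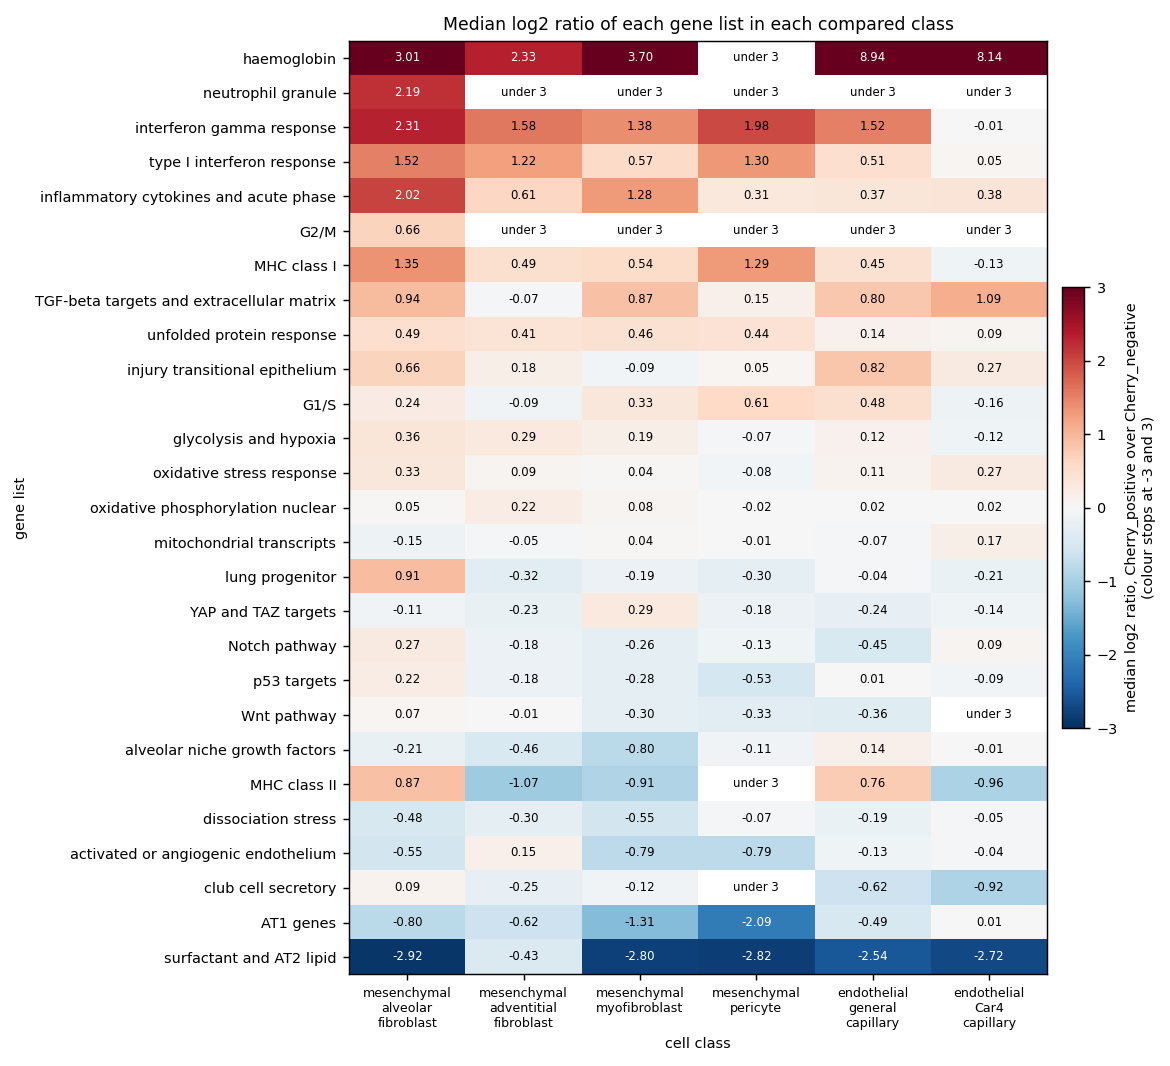
Median log2 ratio of CPM, Cherry_positive over Cherry_negative, of each of the 27 gene lists (vertical axis) in each compared class (horizontal axis), with red for higher and blue for lower, colours stopping at -3 and 3, and "under 3" where fewer than 3 members had 10 UMIs. The interferon gamma list runs from 2.31 in alveolar fibroblasts to -0.01 in Car4 capillary cells, and the surfactant list is below 0 in every compared class.

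Genes of surfactant and AT2 lipids were lower in all compared classes, none of which is epithelial. The surfactant and AT2 lipid list had medians of -2.92 (-3.21 to -2.15) in alveolar fibroblasts, -2.80 (-3.23 to -1.84) in myofibroblasts, -2.82 (-3.75 to -1.41) in pericytes, -0.43 (-1.68 to -0.20) in adventitial fibroblasts, -2.54 (-3.10 to -2.04) in general capillary and -2.72 (-3.30 to -2.20) in Car4 capillary cells. With zero members at their bound the last 2 were -1.18 and -1.30. With 5% of free RNA subtracted the surfactant medians were 0.56 in alveolar fibroblasts, 0.46 in adventitial fibroblasts and 0.0406 in Car4 capillary cells. That subtraction was larger than the Sftpa1, Sftpb and Sftpc levels of these classes in both libraries. Those genes therefore dropped out, and the medians rest on other list members and say nothing about surfactant protein genes. The surfactant protein gene Sftpc was at 161 against 1609 CPM in alveolar fibroblasts. The AT1 list had -0.80 (-1.24 to -0.64), -1.31 (-1.92 to -0.77), -2.09 (-3.50 to -0.72), -0.62 (-1.08 to -0.05), -0.49 (-0.71 to -0.23) and 0.01 (-0.24 to 0.14) in the same order of classes, and -0.41 in general capillary cells with the zero member at its bound. In adventitial fibroblasts the AT1 median was 0.36 with free RNA subtracted and 0.25 without members 10 times higher in another lineage. Most of these genes are expressed by AT2 and AT1 cells, which made up 15.9% and 2.03% of the Cherry_negative library.

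Medians of the remaining lists are given for alveolar fibroblasts, adventitial fibroblasts, myofibroblasts, pericytes, general capillary and Car4 capillary cells in that order, leaving out values printed above. The unfolded protein response list, genes for folding and export of proteins, had 0.41, 0.46, 0.44, 0.14 and 0.09 from adventitial fibroblasts on, the first 3 at percentiles 99.96, 99.97 and 99.52 of random lists. Dissociation stress genes, the immediate early genes that cell isolation induces, had -0.30, -0.55, -0.07, -0.19 and -0.05, the first 2 at percentiles 0.05 and 0. Glycolysis and hypoxia genes had 0.29, 0.19, -0.07, 0.12 and -0.12, nuclear genes of oxidative phosphorylation 0.05, 0.22, 0.08, -0.02, 0.02 and 0.02, and oxidative stress genes 0.09, 0.04, -0.08, 0.11 and 0.27. Mitochondrial transcripts had -0.15, -0.05, 0.04, -0.01, -0.07 and 0.17, the last at percentile 99.3. The p53 targets had 0.22, -0.18, -0.28, -0.53, 0.01 and -0.09, the pericyte value (-0.77 to -0.26, percentile 1.33) with the stress cytokine gene Gdf15 at 47.4 against 204 CPM. The Notch list had 0.27, -0.18, -0.26 and -0.13 in the 4 mesenchymal classes and 0.09 in Car4 capillary cells. Wnt genes had 0.07, -0.01, -0.30, -0.33 and -0.36, the last -0.28 with zero members at their bound, and targets of YAP and TAZ, regulators of tissue growth, had -0.11, -0.23, 0.29, -0.18, -0.24 and -0.14.

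Lists drawn from other cell types were read in the same order of classes. The lung progenitor list had -0.32, -0.19, -0.30, -0.04 and -0.21 from adventitial fibroblasts on, the last -0.07 with its zero member at the bound, and the injury transitional list 0.18, -0.09, 0.05 and 0.27 where not given above. Genes of activated or angiogenic endothelium had -0.55, 0.15, -0.79, -0.79, -0.13 and -0.04. Growth factors of the alveolar niche had -0.21 in alveolar fibroblasts, -0.11 in pericytes, 0.14 in general capillary and -0.01 in Car4 capillary cells. The G1/S list, genes of DNA replication, had 0.24, -0.09, 0.33 and 0.61 in the mesenchymal classes and -0.16 in Car4 capillary cells. Club cell secretory genes had 0.09, -0.25, -0.12, -0.62 and -0.92 without pericytes, the last 0.00 with its zero member at the bound. Haemoglobin genes, which mark red cell RNA, had 3.01, 2.33, 3.70, 8.94 and 8.14 without pericytes, or 1.55 in myofibroblasts with the zero member at its bound, and 1 cell held 98.1% of the haemoglobin UMIs in general capillary and 98.6% in Car4 capillary cells. Fewer than 3 members could be measured for MHC class II, club cell and haemoglobin genes in pericytes, for Wnt genes in Car4 capillary cells, and for neutrophil granule and G2/M genes outside alveolar fibroblasts.

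Cycling cells were few in the named classes. After each cell was thinned to 2000 UMIs, 19 of 850 Cherry-positive alveolar fibroblasts (2.24%, 1.35 to 3.47) and 0 of 388 Cherry-negative ones, which allows up to 0.773% by a limit of 3 counts and 0.946% by the exact interval, held at least 2 UMIs of the G2/M list, genes of mitosis such as Mki67 and Top2a. Thinning left out 18 and 62 shallower cells, and the shares without thinning were 4.95% and 1.33%. The Cherry-positive share was 1.27% when thinned to 1000 UMIs and 0.588% with at least 3 G2/M UMIs. The summed G2/M level was 67.4 against 40.1 CPM, and the list median 0.66 (0.19 to 2.11) with 7 of 7 members higher, at percentile 93.4. As background, the share was 0 of 200 and 0 of 97 in myofibroblasts (up to 1.83% and 3.73% by the exact interval), 1 of 127 and 0 of 110 in adventitial fibroblasts, 0 of 61 and 0 of 26 in pericytes, 1 of 103 and 5 of 496 in general capillary cells and 2 of 75 and 0 of 217 in Car4 capillary cells. In cluster 10 it was 72 of 127 (56.7%, 47.6 to 65.5) and 10 of 10, so free RNA from that cluster, which differed in size between the libraries, remains open for the alveolar fibroblasts.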

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

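Thinning to 2000 UMIs and resolution 0.5 were among the alternative settings, not among those added after the data had been seen. The other tests in this part were chosen only after the result was seen, except the 2 tests on the mix of clusters.

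Cluster 10, which no marker class named, held 7.25% of Cherry-positive cells. It stood out because it was nearly confined to the Cherry_positive library and was in part cycling. The naming rule needed at least 3 detected markers and found 2, so it did not name this cluster as mammary carcinoma either. For the injected mammary carcinoma cells 6 markers had been fixed. In the Cherry_positive library 3 of them had at least 10 UMIs and were at least 10 times higher than in other cells. That bound is not the one of the naming rule and was chosen after the result was seen. Krt14, a basal keratin gene, was at 98.9 against 1.41 CPM and the galectin gene Lgals7 at 187 against 2.71. The third, Cst6, had only 13 UMIs, at 9.59 against 0.824 CPM. Krt17 had 9 UMIs, and Krt6a and Wfdc18 had 0. Injected mammary carcinoma cells are a likely source by this later bound, although mainly by Krt14 and Lgals7. The median AT2, AT1 or club cell marker was at 0.152% of its epithelial level and the median mesenchymal marker at 4.05% of its level. These values argue against AT2, AT1 and club cells and against doublets of lung cells. Of the general epithelial genes, Epcam was at 83.6% and Krt18 at 474% of the epithelial level, but Cldn7 at 15.7%, Cdh1 at 9.36% and Nkx2-1 at 0%. Markers of basal cells were not part of this test, so other lung epithelial cells remain open. The 10 Cherry-negative cells of this cluster had a median of 13688 UMIs against 2985.5 and held endothelial markers at 13.5% of the endothelial level, so doublets with lung cells may explain them. The bound for doublets was set lower for these cells, and 13.5% would not have reached the bound used for the Cherry_positive library. The labels do not say whether the mCherry gate kept or removed injected cells, and no mCherry transcript or genotype was used here.

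Genes induced by interferon gamma stood out in Cherry-positive alveolar fibroblasts and general capillary cells. In general capillary cells a different mix of capillary clusters could account for the difference, because the median was 0.0917 within the largest cluster made without the interferon genes, although other genes that vary with them still shaped that cluster. Free RNA from mesenchymal cells is not a likely source, as it would have to be 54.3 times what mesenchymal markers showed. After thinning the median was 1.37, with 4 Cherry-positive and 280 Cherry-negative shallower cells left out. Random thinning leaves the expected share of each gene in a cell unchanged, and the clusters were those of full depth. The thinned median could therefore hardly fall and does not decide on depth.

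In alveolar fibroblasts the median was 2.25 after thinning, which for the same reason does not decide on depth. Thinning left out 18 Cherry-positive and 62 Cherry-negative shallower cells. In clusters made without the interferon genes the median was 0.52 (0.33 to 0.87) in the largest, and 1.40 (0.96 to 1.81) in another. The first value lies below 0.25 of the median of the whole class, the bound set beforehand for another mix of clusters, but its interval reaches above that bound. These clusters held 15.1% and 23.4% of the Cherry-positive cells and the others had too few Cherry-negative cells, so a change within cells and another mix of alveolar fibroblast clusters cannot be told apart.

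Surfactant genes were lower outside the epithelium in the Cherry_positive library. Free RNA from AT2 cells is a likely cause, since in the Cherry_negative library surfactant protein genes stood at 0.547% to 0.852% of their AT2 level in every compared class, the highest 1.56 times the lowest, while a median of -0.17 in AT2 cells argues against lower surfactant expression by AT2 cells.

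MHC class II genes stood out because they differed between the libraries in opposite directions, higher in general capillary cells (0.76) and alveolar fibroblasts (0.87) and lower in Car4 capillary cells (-0.96) and myofibroblasts (-0.91). Of these 4 signs 3 turned under other settings, with -1.95 and -0.55 in clusters 2 and 6 of the alveolar fibroblasts, -0.0710 in cluster 0 of the general capillary cells and 0.57 in myofibroblasts at resolution 0.5. Single clusters leave out clusters 8 and 12, which interferon-induced genes help to define. That choice tends to lower such medians by construction, so the values in single clusters say little about how stable the signs are. After the result was seen, free RNA of AT2 cells at the level of the surfactant proteins was worked out to bring 63.5 CPM of a gap of 70.9 in Car4 capillary cells and 53.8 CPM for a gap of 50.6 in myofibroblasts. This MHC class II difference between classes was not tested, and no biological explanation was tested for it.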

How the results depend on the processing

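Other settings were tried for the main values, and single clusters, the data without cluster 10 and genes without their top cell were chosen after seeing the data. The cause was not tested except where said. No paired analysis was possible because each group had 1 library and the labels give no replicate numbers, and for the same reason leaving out 1 library at a time and any other split were impossible.

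Without cluster 10 mesenchymal cells made up 79.8% of the Cherry_positive library (74.0% before), by construction through the smaller total. With the libraries clustered separately the interferon gamma median was 0.39 in Car4 capillary cells, 0.98 in general capillary cells and 0.25 in myofibroblasts, the inflammatory median 3.37 in alveolar fibroblasts, and MHC class I in myofibroblasts -0.0375 instead of 0.54.

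With 5% of free RNA subtracted the interferon gamma median of Car4 capillary cells was -0.59. Signs turned for matrix genes in Car4 capillary cells (-0.13), inflammatory genes in general capillary cells (-0.0467) and AT1 genes in adventitial fibroblasts (0.36). The surfactant list was at 0.0406 in Car4 capillary cells, 0.46 in adventitial and 0.56 in alveolar fibroblasts. These surfactant values leave out Sftpa1, Sftpb and Sftpc, which the subtraction took away entirely in both libraries. Without members 10 times higher in another lineage the interferon gamma median was 0.93 in adventitial and 1.97 in alveolar fibroblasts, the inflammatory median 1.59 in alveolar fibroblasts, and signs turned for AT1 genes in adventitial fibroblasts (0.25) and injury genes in alveolar fibroblasts (-0.0904).

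Within cluster 0, the largest part of the general capillary class, the interferon gamma median was 0.13, and type I interferon (-0.43), MHC class I (-0.14) and MHC class II (-0.0710) turned sign. Within cluster 2 of the alveolar fibroblasts interferon gamma was 0.25, MHC class I 0.20 and inflammatory genes 0.86, and lung progenitor (-0.0307), MHC class II (-1.95) and glycolysis genes (-0.0757) turned sign. Within cluster 6 these were 1.13, 0.18 and 1.001, and injury (-0.15), MHC class II (-0.55) and dissociation stress genes (0.0914) turned sign. Such single clusters leave out clusters 8 and 12, which interferon-induced genes help to define. Lower interferon and MHC medians within them are therefore in part built in.

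At resolution 0.5 MHC class I was 1.21 in alveolar fibroblasts, interferon gamma 2.03 in myofibroblasts and MHC class II 0.57 in myofibroblasts, the last with its sign turned. Members with at least 1 UMI gave 1.84 for inflammatory genes in alveolar fibroblasts, and a trimmed-mean factor gave 1.54 for interferon gamma in myofibroblasts. For the named genes, separate clustering of the libraries put 25 log2 ratios outside their main interval and left 53 inside. Thinning to 2000 UMIs put 26 outside and left 62 inside, and no sign turned under either setting. Without their top cell the log2 ratios of Acta2 and Tpm2 in Car4 capillary cells were 1.74 and 0.60, with the sign turned. Taking out a top cell shrinks a difference by construction, but it turned the sign of no other named gene. For Glycam1 in general capillary cells it left 0 UMIs in both libraries, so its sign comes only from the 0.5 added to each count. Cycling alveolar fibroblasts of the Cherry_positive library were 4.95% without thinning, 1.27% thinned to 1000 UMIs and 0.588% with at least 3 G2/M UMIs, against 2.24%, and those of the Cherry_negative library 1.33% without thinning, against 0.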

Other observations

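AT2 cells were too few for the comparison, with 22 Cherry-positive and 447 Cherry-negative cells. In them the interferon gamma list had a median of 1.73 (1.15 to 2.31) with 12 members higher and 0 lower, the surfactant list -0.17 (-0.26 to -0.07) and MHC class II genes 0.06. In the same 22 cells the matrix list had 1.996 with 16 of 17 members higher, and 1 cell held 82.7% of the UMIs of Mgp, 83.3% of those of Vcam1 and 88.9% of those of Igfbp4, which mesenchymal cells also express. The lysozyme gene Lyz1 was at 6490 against 14499 CPM. Retnla, an inflammation gene, was at 4360 against 210 CPM, with 92.0% of its UMIs in 1 cell.

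In cluster 10 of the Cherry_positive library the epithelial keratin genes Krt8 and Krt18 were at 1075 and 1039 CPM against 13.2 and 19.2 in other cells.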
